A study of Mus musculus with 7 samples.

How the data were processed

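Nuclear RNA-seq (2 libraries), H3K4me3 ChIP-seq (2 libraries) and ChIP input (1 library) were made from flow-sorted Rag1-/- mouse pro-B cells, and VDJ-seq (2 libraries) from wild-type pro-B cells, per the labels. The titles of the ChIP samples read H4K4me3, while the design text, the antibody entry and the file header all say H3K4me3, the name used here. The submitters' processing notes name Trim Galore 0.4.0, Bowtie and MACS and the mouse genome build NCBIM37 (mm9), without saying which step used which. Aligner settings, the removal of duplicate reads and the libraries on which peaks were called are not given in the sources used here.

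The VDJ-seq values are whole-number counts per V gene as deposited by the authors, taken here as reads. The table is named unique, and whether that means deduplicated or uniquely mapped reads is not given. The table has no header, so its 2 columns are called the first and the second library, and neither could be tied to a replicate number. The RNA values per 1 kb window and the ChIP and input values per listed region are RPM per the file headers. As deposited they are on a log2 scale, since they include negative values, and they were read as log2 RPM. Within each column the values were whole multiples of a single step for at least 99.99% of entries (tolerance 0.05 read), and entries without reads stood at 0.9 read and were set to 0. The step gave each library's total. In the RNA libraries 60.7% and 59.5% of counts from 1 to 50 were even, and windows summed to 1042545 and 1038670 RPM, which exceeds 1 count per read. The labels call the RNA libraries strand-specific, and the windows carry no strand. The lowest replicate 2 count in any listed region was 18 reads, while 63 regions held no replicate 1 read, so the list may lean to regions strong in replicate 2.

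The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16. Each V gene was tested with an exact binomial test against the even share and, between libraries, with Fisher's exact test. Families of at least 5 genes, position, pseudogene marks, RNA and H3K4me3 were tested with two-sided permutation tests (100000 resamples) on ranks. Family and pseudogene status were read from the gene names. RNA at a V gene or region is the mean RPM of the windows it overlaps. Enrichment over input was tested with limma (eBayes with trend) on log2(RPM + 0.1), which understates the change of low regions and leaves 1 residual degree of freedom per region. edgeR's quasi-likelihood test on the recovered reads, with library totals and no further scaling, was an alternative. Adjusted p-values are Benjamini-Hochberg, and the threshold was 0.05. The Igh locus was taken as 114509484 to 117248176 on chromosome 12, the span of the listed V genes and the Igh genes annotated in GENCODE vM1. Lengths of all 22 chromosomes in the RNA table matched NCBIM37, and 91 V gene starts equalled an annotated one. Promoter regions of listed genes lie within 1 kb of a transcript start. Older symbols were matched through RefSeq synonyms, and 6 list members without a single annotated gene were left out. A share listed at no reads allows up to 3 counts of the total, and such limits cover counting error only.

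The scripts were tested on simulated data. Against even use over 195 genes, 100% of genes at 0.5 and at 1.5 times the share were called and 0.739% of unchanged genes. For peaks over 19228 regions, limma called 15.5% of regions at 2-fold, 57.0% at 4-fold, 94.0% at 8-fold and 0 of 200 unchanged ones, and edgeR called 19.0%, 63.5%, 94.0% and 0.5%. Between libraries over 195 genes, 99.75% of genes at 1.5 times were called. For a family of 20 among 195 genes, 5.5% of tests without a shift and 96.5% with a shift of 1 SD passed an unadjusted p under 0.05. Smaller families, such as J606 with 5 genes, and the adjustment over families were not simulated. Over 195 genes, 4.5% of correlations without a relation and 99.0% with a slope of 0.3 passed, also unadjusted.

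Tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those the text gives as chosen after. The design assumed linear RPM, and the deposited log2 values were converted to RPM first. The rule named the 10 most and 5 least used called V genes, the top gene of each family, the 5 genes that differed most between libraries, V genes with a nearby region, the 10 highest regions and windows, the Igh regions and the list members, the text giving the extreme members of each. Some V genes are given by family and position in place of their name. Alternatives were other reference shares, pooled counts, filters on low counts, other scalings, pseudocounts, thresholds and distances, and leaving out each library. A sense-strand alternative was not run because the windows carry no strand.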

Results

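The data came from mouse bone marrow pro-B cells, the progenitors in which the immunoglobulin heavy chain (Igh) locus joins a V gene to a DJ segment. VDJ-seq, which sequences recombined Igh DNA, was made from wild-type C57BL/6 cells in 2 libraries. Nuclear RNA-seq (2 libraries), ChIP-seq of the promoter-associated histone mark H3K4me3 (2 libraries) and 1 input DNA library came from Rag1-/- cells. Those cells lack the RAG1 recombinase subunit, so their Igh locus stays unrearranged. The first VDJ-seq count column held 220363 reads in V genes and the second 239090. The value of a single read put the RNA libraries at 33140855 and 28221601 reads, the ChIP libraries at 8856764 and 25729880, and the input at 52736682. Nuclear RNA over the targeted gene Rag1 was 41.0 RPM in replicate 1 and 32.8 in replicate 2. The labels do not give which part of Rag1 the allele removes, so this value checks nothing about the genotype. The labels do not say whether replicates were separate mice, so spreads and p-values cover these libraries only.

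The first comparison asked how unevenly V genes were used. A J-proximal gene of the 7183 family, at chromosome 12 from 114816715 to 114817021 (NCBIM37), held 6.73% ± 0.35 (SD, n = 2) of V gene reads, 13.1 times the even share. Q52.2.4 followed with 3.56% ± 0.021, then J558.26.116 with 2.93% ± 0.0027 and 7183.4.6 with 2.79% ± 0.029. J558.16.106 held 2.35%, J558.8.98 held 2.26%, 36-60.6.70 held 2.01%, VH12.1.78 held 1.82%, VGAM3.8-3-61 held 1.81% and J558.1.85* held 1.68%. These 10 genes together held 27.9% of reads, and 26 of the 195 listed genes held 50% of them. In exact two-sided binomial tests against the even share of 0.513%, 66 genes lay above it and 116 below it in both libraries, at a Benjamini-Hochberg adjusted p under 0.05 in each. Among called genes with reads in both libraries, the lowest were a 7183 pseudogene at 114925438 (0.000436%), J558.63pg.159 (0.000890%), J558.68pg.168 (0.00108%), a 7183 pseudogene at 114828176 (0.00150%) and PG.10.56 (0.00157%). Each of these shares rests on 1 to 6 reads per library, so their order is within counting error. No read fell in 33 genes, which allows each a share of up to 0.00136% in the first library and 0.00125% in the second. These limits and the binomial test cover counting error only, and take each read as an independent molecule, which PCR duplicates would not be; their removal is not recorded.

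**Figure D1:**
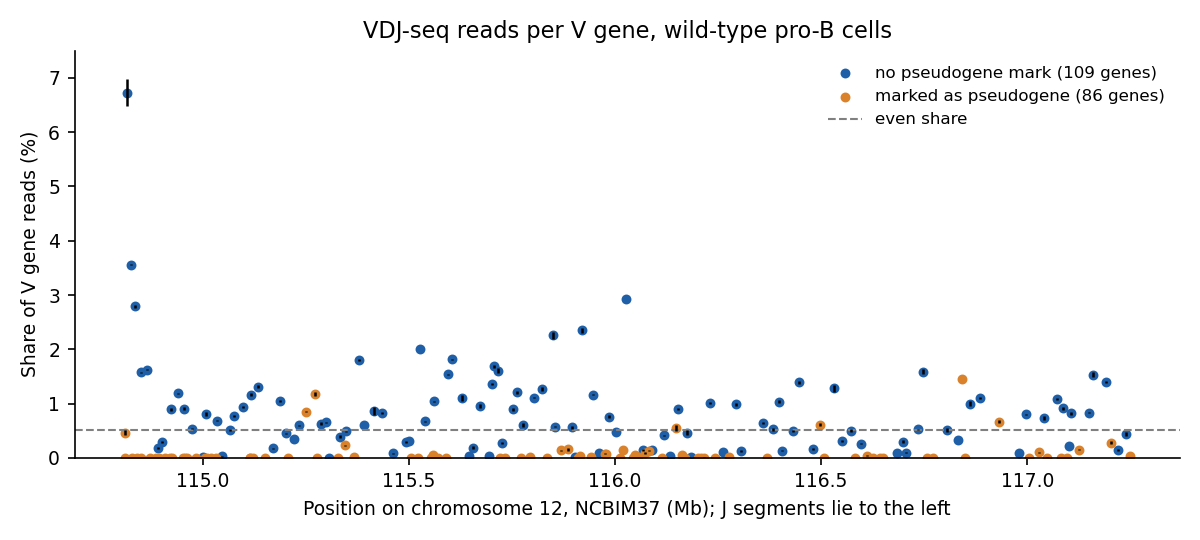
Share of V gene reads (%) against position on chromosome 12 (NCBIM37, Mb) for 195 V genes, where points are means of 2 libraries, black lines join their values, orange marks the 86 genes named as pseudogenes and the dashed line is the even share of 0.513%. The highest point, at 6.73%, is the 7183 gene at 114816715, and most orange points lie near 0%.

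Pseudogenes were used far less than the other V genes. The 109 genes without a pseudogene mark in their name held 92.3% of reads with a median share of 0.656%, and the 86 marked genes held 7.70% ± 0.38 with a median of 0.000785%. The difference in mean rank was 83.7 places (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). All 33 genes without reads carried the mark. The rule was not absolute: the pseudogenes J558.70pg.171 (1.45%), a 36-60 pseudogene at chromosome 12 from 115272014 (1.18%), X24.2pg.50_ (0.853%), J558.73pg.175 (0.669%) and a 3609 pseudogene at 116496343 (0.611%) lay above the even share. Conversely, 37 genes without the mark lay below it, down to VH16.1.55, with 1 read in the first library and 20 in the second. These 5 pseudogenes and VH16.1.55 were named after their values were seen.

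The 2 libraries gave nearly the same V gene order. Across the 195 genes, shares had a Pearson r of 0.998 and a Spearman rho of 0.992 (permutation p = 1e-05 for each, the smallest that resampling can give; genes are not independent replicates). Among the 95 genes with at least 1000 reads, the median coefficient of variation between libraries was 3.53%. By Fisher's exact test, which also takes each read as an independent molecule, 20 genes differed at an adjusted p under 0.05, of which 12 were higher in the second library. If some reads are PCR duplicates, fewer molecules were counted and these p-values are too small. By p-value the 7183 gene at 114816715 differed most, with 6.48% in the first library and 6.98% in the second (adjusted exact p = 3.5e-09). J558.38pg.128 (0.489% and 0.613%) and a 7183 pseudogene at 114811138 (0.418% and 0.513%) were also higher in the second library, and SM7.4.63 (0.928% and 0.798%) and J558.42.132 (0.514% and 0.419%) were higher in the first. The largest ratios among the 20 came from few reads, at VH16.1.55 (1 and 20 reads) and a 3609 pseudogene at 117046638 (14 and 1), both named after their values were seen.

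Families of V genes held unequal shares of reads, while only a single name group differed from the rest in the rank of its genes. The 89 J558 genes, the large distal family, held 42.5% ± 0.12 of reads, the 21 genes of the proximal 7183 family held 15.9% ± 0.40, and the 13 Q52 genes held 9.80% ± 0.14. The 8 genes of 36-60 held 6.11%, the 16 of 3609 held 5.34% and the 5 of J606 held 2.32%. Their most used members were J558.26.116, the 7183 gene at 114816715, Q52.2.4, 36-60.6.70, 3609.1.84* (1.36%) and J606.1.79 (1.10%). Only the 19 pseudogenes named PG, led by PG.11.58 at 0.228%, differed from the rest among 7 name groups tested, with a lower mean rank (difference -71.6, permutation p = 1e-05, the smallest that resampling can give, adjusted p = 7e-05). Adjusted permutation p-values of the other 6 groups lay between 0.370 for 36-60 and 0.557 for J606 and Q52. The direction of J558, 7183 and J606 turned once genes without reads or with a pseudogene mark were left out, so no direction is given for them. Genes are not independent replicates.

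No relation of use with position along the locus passed the test. The 65 V genes nearest the J segments held 38.2% ± 0.060 of reads, the middle 65 held 34.4% ± 0.010 and the distal 65 held 27.4% ± 0.050. The proximal total included the 7183 gene at 114816715, Q52.2.4 and 7183.4.6. Median shares were 0.228%, 0.146% and 0.218%, and 24, 22 and 20 genes in turn lay above the even share. Across all 195 genes, use and rank from the J end had a Spearman rho of 0.0651 (permutation p = 0.368) and a Pearson r of -0.116 (p = 0.107). The rho was -0.143 (permutation p = 0.138) over genes without a pseudogene mark, a set chosen after seeing the data.

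H3K4me3 marked promoters across the Rag1-/- pro-B genome. Of 19228 listed regions, 16145 (84.0%) stood above input at an adjusted p under 0.05 in limma with a log2 fold change of at least 1. The median log2 fold change was 3.15, and 18569 regions (96.6%) reached a log2 fold change of 1 in each replicate. The list was itself chosen by peak calling, so a high share above input follows in part from that choice. An annotated transcription start lay within 1 kb of 13269 regions (69.0%), which had a median log2 fold change of 3.48 against 2.40 at the other 5959. Regions held 23.1% of reads in replicate 1 and 23.3% in replicate 2, against 2.13% of input reads. Among the 10 highest called regions by mean ChIP RPM were the surrogate light chain locus of Igll1 and Vpreb1 (chromosome 16 from 16859251 to 16872750, mean 148 ± 45, log2 fold change 4.14 ± 0.51 SE), the Ets factor gene Erg (155 ± 31, 4.41 ± 0.51) and B3gnt2 (159 ± 33, 3.80 ± 0.53), with SD and n = 2 for the RPM. The other 7 differed widely between replicates: 6 had more RPM in replicate 1, namely 4 at chromosome 9 between 3011251 and 3038400, 1 at chromosome 9 from 35112601 (2744 and 82.5 RPM) and 1 at chromosome 12 from 3109651 (2112 and 35.5 RPM). The last, in the light chain Igk locus at chromosome 6 from 69247501 to 69317850, had 23.7 RPM in replicate 1 and 321 in replicate 2. With a single input library, the test's spread came from the ChIP pair alone, and eBayes pooled it over regions. The SE therefore need not follow the replicates of a given region. It was 0.52 in that Igk region, with log2 ratios to input of -0.42 in replicate 1 and 3.33 in replicate 2. At Erg the SE was 0.51, with ratios of 4.20 and 4.61. The Igk region was called although its replicate 1 stood below input.

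At the Igh locus, H3K4me3 was strongest at the J segments and at intergenic sites among distal V genes. The region from 114660751 to 114670650 on chromosome 12, which spans the J segments and the intron before Ighm, had 98.7 RPM in replicate 1 and 186 in replicate 2, with a log2 fold change over input of 4.56 ± 0.51 (SE, adjusted p = 1.39e-16). Next came an intergenic region from 116645101 to 116650800, beside PG.19.161, with 58.6 and 66.3 RPM (4.21 ± 0.49). Another, from 116500501 to 116505600 upstream of the 3609 pseudogene at 116496343, had 43.5 and 45.9 RPM (3.72 ± 0.50). These 3 regions ranked in the top 2% of all regions by mean ChIP RPM. Intergenic repeats upstream of 3609 genes are known to be transcribed in pro-B cells. A further intergenic region from 115616401 to 115618800 near J606.1.79 had a log2 fold change of 3.49 ± 0.59. In all, 13 listed regions lay in the locus, 11 of them among the V genes, and 10 were called. Of these 13, 7 overlapped a V gene: SM7.2.49, 3609.1.84*, J558.23.113*, J558.72.173, J558.75.177, J558.78.182 and J558.84.190. Those had log2 fold changes from 1.74 to 2.48, and J558.75.177 (adjusted p = 0.0649) and J558.78.182 (0.0989) were not called. All 7 had more RPM in replicate 1 than in replicate 2.

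Nuclear RNA at the unrearranged Igh locus was highest per window near Ighm and at distal intergenic sites. Counting windows wholly inside a part of the locus, the 8 from Ighm to the J segments averaged 121.04 RPM ± 11 (SD, n = 2) and held 25.8% of the locus RPM. The 2436 of the V gene region held 47.0%, the 149 over constant genes other than Ighm 15.5%, and the 6 left out 8.90%. Those 149 took in the window from 114658001 and had a median of 0.0302 RPM, so 15.5% need not be RNA of those genes. Windows left out on the borders of Ighm and the J segments were high, at 114659001 (147 and 145 RPM) and 114668001 (233 and 143 RPM). With border windows counted, the 10 from Ighm to the J segments held 34.7%. The highest single window, 1 kb from 114658001 just downstream of Ighm, had 225 and 187 RPM, and 9 of the 10 highest windows of the locus lay between it and 114669000. The tenth was at 116655001, an intergenic stretch upstream of PG.19.161, with 72.3 and 94.2 RPM. All of the 9 highest windows among V genes lay from 116646001 to 116657000, either in the H3K4me3 region there or next to it, and the next was at 116522001 (56.5 and 38.9 RPM). The D segments averaged 1.08 RPM ± 0.22, or 2.96 ± 0.43 with the windows on their borders, the stretch from the D segments to the first V gene 0.00954 ± 0.012, and the V gene region 0.724 ± 0.091. Windows with reads in both replicates made up 78.8%, 4.35% and 30.5% of those overlapping each part. Across the locus 887 of 2740 windows (32.4%) held reads in both replicates, and the mean of 1.37 RPM ± 0.0067 lay above 97.53% of 10000 random autosomal stretches of the same length, whose median was 0.213. That small SD depends on the RPM totals, of which the highest windows of the genome took unequal shares in the 2 replicates. Requiring more than 0.1 RPM left 22.5% of windows. The median window of the locus had 0.0177 RPM, against 0 genome-wide, so the high mean came from a minority of windows.

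**Figure D2:**
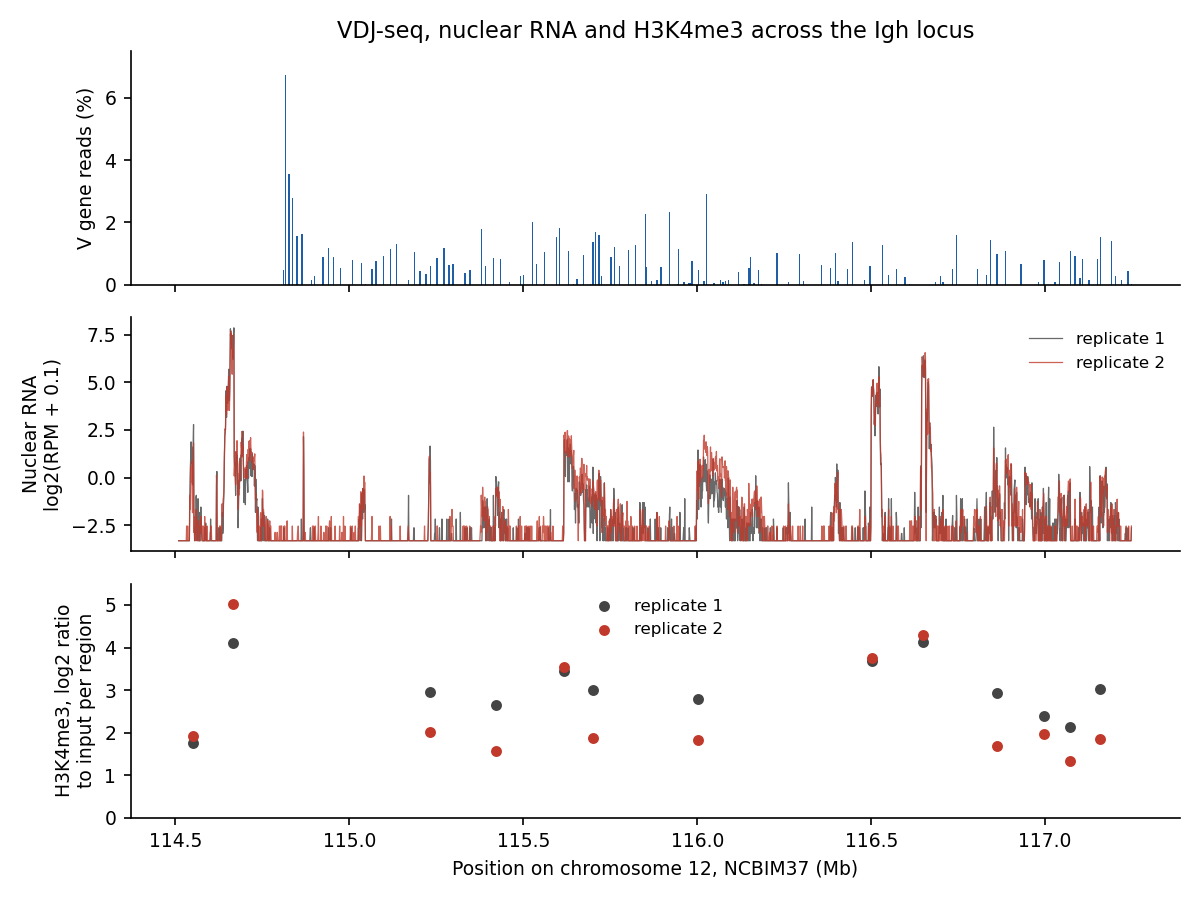
The Igh locus on chromosome 12 (NCBIM37, Mb), where bars in the top panel are mean shares of V gene reads (%), lines in the middle panel are nuclear RNA per 1 kb window as log2(RPM + 0.1) in each replicate, and points in the bottom panel are log2 ratios of H3K4me3 to input at 13 listed regions in each replicate. RNA is highest from just downstream of Ighm (225 and 187 RPM at 114658001) to the J segments and near 116655001 (72.3 and 94.2 RPM), in or beside the regions with the highest H3K4me3 ratios.

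Genome-wide, a few windows held much of the nuclear RNA. Of the 10 highest windows, 6 were consecutive, at chromosome 17 from 39980001 to 39986000, a stretch known to carry a ribosomal RNA precursor copy, with up to 118533 RPM in replicate 1 and 40291 in replicate 2. The others lay in Filip1l (chromosome 16 from 57391001, 55217 and 10566 RPM), at chromosome 3 from 5860001, in Zc3h7a over mmu-mir-689-2, and in Lars2. These 10 windows took 29.1% of all RPM in replicate 1 and 11.4% in replicate 2. The RPM totals include them, which lowers replicate 1 values elsewhere relative to replicate 2. Differences and SDs between RNA replicates therefore depend on this scaling, and no other RNA scaling was tried. Over windows with reads in both, log2 RPM of the replicates had a Pearson r of 0.844 and a Spearman rho of 0.856.

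Regions with more H3K4me3 held more nuclear RNA. The median RNA rose from 0.0354 RPM ± 0.0037 in the 4807 regions lowest in H3K4me3, through 0.140 ± 0.012 and 0.564 ± 0.023, to 1.33 ± 0.031 in the 4807 highest (SD of the replicate medians, n = 2). In the lowest group the replicate medians, 0.0302 and 0.0354 RPM, equal 1 read in each library, so that SD reflects depth only. Annotated transcription starts lay within 1 kb of 45.2% of regions of the lowest group and 94.7% of the highest. Of windows with an H3K4me3 region 71.2% held RNA in both replicates, against 18.4% of windows without one. Across the 19228 regions, mean ChIP RPM and RNA RPM had a Spearman rho of 0.561 and, on the log2 scale, a Pearson r of 0.524 (two-sided permutation p = 1e-05 for each, the smallest that resampling can give). ChIP RPM is a total over regions of 300 to 70350 bp, so region length enters it. With H3K4me3 per kb of region rho was 0.476, and over regions within 1 kb of a transcription start it was 0.687 (permutation p = 1e-05 for each). Both were chosen after seeing the data. Regions are not independent replicates.

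**Figure D3:**
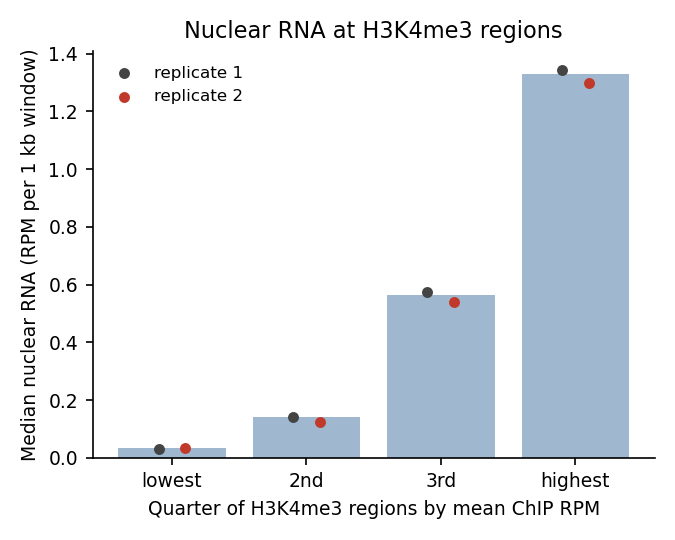
Median nuclear RNA (RPM per 1 kb window) at H3K4me3 regions in 4 groups of 4807 by mean ChIP RPM, where bars are medians of the mean of both replicates and points the median in each. Medians go from 0.0354 in the lowest group to 1.33 in the highest.

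The next comparison asked whether V genes that recombined more often lay in chromatin with more RNA or H3K4me3 before recombination. Of the 10 most used genes, the 7183 gene at 114816715, Q52.2.4, 7183.4.6, 36-60.6.70 and VH12.1.78 lay in windows at 0 RPM in both replicates, and J558.26.116 in windows at 0.664 and 3.44 RPM. The unused PG.19.161 lay in windows at 42.1 RPM. The median V gene lay at 0.0479 RPM, and 83 of the 195 had RNA in both replicates. Genes without a pseudogene mark had a median of 0.0732 RPM and pseudogenes 0.0171, a difference of 18.5 in mean rank (permutation p = 0.0191, not adjusted). This test was not among those fixed before the data were examined. Both medians lay below the value of 3 reads, 0.0905 RPM in replicate 1 and 0.106 in replicate 2. Across all V genes, use and RNA had a Spearman rho of 0.145 (permutation p = 0.0423, adjusted p = 0.253 over 6 relations) and a Pearson r of -0.0567 (p = 0.347). Without the first VDJ-seq column and RNA replicate 1, rho was 0.0749 (adjusted permutation p = 0.812). Without the 2 genes farthest from the median RNA, rho was 0.169 and r 0.0738. Within 3609, J558, 7183, Q52 and PG, adjusted permutation p-values lay between 0.253 and 0.967, and over genes without a pseudogene mark, chosen after seeing the data, rho was -0.0819.

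V genes with a listed H3K4me3 region within 1 kb were used more often than the rest by a narrow margin, which was lost when only called regions counted. The 8 genes were PG.19.161 and the 7 whose sequence a region overlapped, led by J558.84.190 (1.53%), 3609.1.84* (1.36%), J558.78.182 (1.08%) and J558.72.173 (0.997%). Their median share was 0.902% against 0.152% for the other 187, a difference of 40.02 in mean rank (two-sided permutation p = 0.0478), and 6 of the 8 lay above the even share. Of the 187 other genes, 60 also lay above the even share, the 7183 gene at 114816715 among them. The regions over J558.78.182 and J558.75.177 were not called over input, and with the 6 genes near called regions the difference was 33.5 (permutation p = 0.154). It was 24.04 (permutation p = 0.172) with a distance of 5 kb and 16.2 (permutation p = 0.197) over genes without a pseudogene mark. For the 7 genes that a region itself overlapped, which leaves out PG.19.161, it was 57.5 (permutation p = 0.00584). The called regions and the unmarked genes were chosen as alternatives after seeing the data.

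Genes of the pro-B cell programme carried both promoter H3K4me3 and nuclear RNA. Of 13 measured pro-B transcription factors, all 13 had a called promoter region and RNA in both replicates. Their median of 11.2 RPM per window lay at percentile 100 among the medians of 10000 random lists of protein-coding genes. The B lineage, recombination and DNA repair, chromatin architecture and nuclear RNA lists also lay at percentile 100, so this rank is not particular to these factors. Of all protein-coding genes, 54.2% had a listed region within 1 kb of the gene's start. That share counts regions called or not and only the gene's 5' end. List members were matched at any transcript start, so the shares are not measured alike. Ebf1, a factor that specifies B lineage, had 39.1 RPM ± 17 (SD, n = 2) with a log2 H3K4me3 fold change of 4.45, and Pax5, which commits cells to it, 14.8 and 17.2 RPM with 4.27. Spi1 was lower, at 0.605 RPM, and Ikzf3 at 0.339. All 15 B lineage receptor and signalling genes were called and had RNA, with a median of 10.2 RPM. They included the coreceptor gene Cd19 (64.4 ± 0.14), the surrogate light chain gene Igll1 (56.2 ± 14) and the linker gene Blnk (29.8 ± 3.2). Vpreb1 had 28.0 RPM in replicate 1 and 8.65 in replicate 2.

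The recombination machinery was also transcribed. Of 13 recombination and DNA repair genes, 12 had a called promoter region, and all 13 had RNA, with a median of 2.88 RPM. Rag1 had 36.9 RPM ± 5.8, Dntt, which adds N nucleotides at junctions, 23.3 ± 0.45 and Rag2 14.7 ± 0.35. Nhej1 had no region and 0.253 RPM. All 9 chromatin architecture genes were called, Smarca4 having the most RNA (27.2 ± 0.24) and Ctcf 3.98 ± 0.73. Counts of called members were the same in every list when adjusted over the list alone.

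Marker lists of other cells lay well below the pro-B lists in nuclear RNA. Only the T cell and NK lists had a median below that of the median protein-coding gene, which had 0.150 RPM per window. The T cell markers had a median of 0.0174 RPM, with Cd3e and Cd3g at 0 in both replicates, although the promoters of Lck and Gata3 were called. Of the myeloid markers, with a median of 0.350 RPM, Lyz2 had 0.718 and S100a9 0.710, and 2 of 9 promoters were called. Erythroid markers had a median of 0.165 RPM, with Hbb-b1 highest at 3.12 and 2.87 and 3 of 7 promoters called. NK markers had a median of 0.0630 with 2 of 5 called. Stem and early progenitor markers had a median of 0.194 RPM, with Kit at 0.739 and Flt3 at 0.315, and 4 of the 6 in that list were called. Mature B cell markers had a median of 0.181 RPM, with Cr2 at 0.653 and 1 of 4 called. Medians of these 6 lists lay above 23.8% to 66.7% of random lists. RNA in both replicates was present at 7 of 9 T cell, 8 of 9 myeloid, 7 of 7 erythroid and 4 of 5 NK markers. It was also present at 5 of 6 stem and early progenitor and 4 of 4 mature B cell markers, so its presence did not set the lists apart. Of the nuclear noncoding RNAs, Malat1 had 605.9 RPM ± 182, Xist 55.0 ± 12 and Neat1 5.75 ± 0.65, while Meg3 stood at 0, and 3 of 4 promoters were called.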

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

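Of 88 values recomputed under alternatives for 19 results, 71 kept their direction and side of the threshold or, without a test, stayed within 1.5 times for counts and within 1 SD for other values, among them 32 of the 34 that left out a library. Tests over genes without a pseudogene mark, use at called regions, and RNA against H3K4me3 per kb or at transcription starts, were chosen after seeing the data (13 values). Against a share of 2 times the even share, 30 V genes lay above it in place of 66, which follows from the higher reference. Called regions ranged from 12263 (pseudocount 1) to 17167 (edgeR, 15774 shared with limma) around 16145, and from 18574 to 19220 without a test when 1 replicate was left out. No family differed over genes without a pseudogene mark (0 in place of 1), because the PG group is then gone.

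Directions that were never past the threshold turned. With genes without reads left out, the mean rank difference became 1.54 for 7183, -4.83 for J558 and -1.34 for J606, and rho with position -0.0663. Over genes without a pseudogene mark these were 11.2, -4.97, -17.6 and -0.143, and rho of use with RNA was -0.0819. That rho was 0.0749 (adjusted permutation p = 0.812) without the first VDJ-seq column and RNA replicate 1, and 0.157 (0.0883) without the second column and replicate 2. The difference in use at H3K4me3 lost its call at 5 kb (24.04, permutation p = 0.172), over genes without a pseudogene mark (16.2, permutation p = 0.197) and with called regions only (33.5, permutation p = 0.154), while for regions over the gene itself it was 57.5 (permutation p = 0.00584). Only 3 genes had a nearby region among those above the median ChIP RPM, too few to test. The share of Igh windows with reads was 22.5% above 0.1 RPM and 39.7% to 45.9% in single replicates, as a window then needs reads in 1 library. The cause of the other changes was not tested.

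No paired analysis was possible because the ChIP and the input share only 1 replicate number, the VDJ-seq columns carry none, and the other assays were not compared with each other as groups. The 8856764 reads of ChIP replicate 1 limit weak regions, since 3 reads there equal 0.339 RPM.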

Other observations

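Among antigen receptor loci, as bounded here, Igh held the most nuclear RNA per window in both replicates. The Igh bounds took in its constant genes, while the Igk bounds took in V and J genes only. The V gene region of Igh alone averaged 0.724 RPM. The Igk locus (chromosome 6 from 67505630 to 70673921) averaged 0.0505 RPM ± 0.0040 (SD, n = 2) per 1 kb window of nuclear RNA against 1.37 at Igh, and 7.95% of its windows held reads in both replicates against 32.4%. The Igl locus averaged 0.0645 ± 0.013 with 22.4% of windows and no listed H3K4me3 region. The T cell receptor loci were nearly silent: alpha had 0.712% of windows with reads, beta 2.10% and gamma 0.568%, and their means were 0.00257, 0.00728 and 0.00314 RPM. The alpha locus held 4 listed regions, of which 2 were called.

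The tests of the signal and of shared sequence over unmarked V genes were stated before their results were seen, and all other tests in this part were chosen after. V gene use may follow the recombination signal next to each gene. The bases matching the consensus heptamer CACAGTG and nonamer ACAAAAACC were counted out of 16. The best match near the gene's 3' end was taken among sites that begin with CAC, the heptamer start, so low matches need not be true signals. Pseudogenes without such a start, 12 without reads and 6 with reads, were left out. Among 68 pseudogenes with a heptamer start, this match had a Spearman rho of 0.737 with use (permutation p = 1e-05, the smallest that resampling can give; 95% bootstrap interval 0.610 to 0.823). Median use went from 0% at a match of 10 or fewer (29 genes) through 0.00664% at 11 to 13 (20 genes) to 0.107% at 14 or more (19 genes, none without reads). Among these 68 pseudogenes with a heptamer start, rho was 0.713 over the 47 with reads and 0.729 within the 35 of J558. The relation had exceptions, such as the 3609 pseudogene at 116496343, with a match of 10 and a share of 0.611%.

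Over the 109 genes without a pseudogene mark, whose median match was 14, rho was 0.149 (permutation p = 0.122, interval -0.0651 to 0.348), which leaves a weak relation open. A technical candidate explanation is loss of reads shared by near-identical genes, if only uniquely mapped reads were counted. The share of a gene's 50-mers found elsewhere in the locus had a rho of -0.209 with use over those 109 genes (permutation p = 0.0287, adjusted p = 0.0574 over both relations), in the direction that loss would give. Over pseudogenes rho was -0.0120 (p = 0.913, interval -0.217 to 0.188), which leaves such a loss open there.

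A stretch of the Igk locus (chromosome 6 from 69199951 to 69326850, 8 listed regions) had 12.2 times as much H3K4me3 RPM in replicate 2 as in replicate 1, where it stood at 0.812 times input. A different depth or scaling of replicate 2 is argued against by a median log2 ratio of 0.11 over all regions, against 3.36 in the stretch. Extra copies of this DNA in the replicate 2 library could produce it: the log2 ratio of replicate 2 to input had an SD of 0.10 across the 8 regions, below all 19069 other runs of 8 neighbouring regions (median 0.95, lowest 0.14). Once regions with fewer reads than any in the stretch were left out, which makes other regions neighbours, the 12858 runs had a median of 0.65 and a lowest SD of 0.12. The SD cannot decide on extra copies. The stretch was extended from the longest listed region while each neighbour had a log2 ratio of replicate 2 to replicate 1 above 2. Its regions cover 121950 bp of a nearly unbroken block, while regions of other runs can lie far apart. A lower SD may follow from that choice alone. A broad mark in the replicate 2 cells stays open, and no biological explanation was tested.

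All 7 regions over V genes had more H3K4me3 RPM in replicate 1 than in replicate 2 (median log2 ratio 0.97), against 1 of the 6 other Igh regions. This split is confounded with strength: the 7 had mean RPM of at most 10.7, and most of the others had more. Of the weak others, the region from 115421401 leaned to replicate 1 (7.11 and 3.30 RPM). The region from 114550501 did not (2.82 and 3.15 RPM). A general lean of weak regions to replicate 1 would give medians from -0.49 to 0.93 in random regions matched on RPM and length, and 1.61% of 10000 draws reached the observed value. The test was chosen because this lean had been seen, which can make that share too low. It therefore cannot decide on a general lean. Reads shared by near-identical sequence may still contribute: 33.5% of 50-mers in the V gene regions lay elsewhere in the locus against 15.3% in the others (exact permutation p = 0.158). The regions are too few to tell whether that difference matters, and no biological explanation was tested.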
